A study of Caenorhabditis elegans with 2 samples.

How the data were processed

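Binding of SEM-2 was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in 2 biological replicates, numbered 1 and 3, of mixed-stage C. elegans embryos carrying a SEM-2-eGFP transgene. Per the labels, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP. The labels give the replicates as separate biological samples of 1 group. No second condition was sampled, so the comparisons were made between the replicates, between peak positions and shifted positions, and between target genes and all annotated genes. A control experiment is named in the labels; its reads and peaks were not analysed here.

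The deposited files were 4 peak lists in narrowPeak format on the ce11 assembly, per the labels. Each replicate had a list of peaks and background made as input for an analysis of the irreproducible discovery rate (IDR). The authors also made such a list from the reads of both replicates together, here called the combined list, and a thresholded list of peaks that passed the IDR analysis. The peak caller, the aligner, the IDR software with its version and the IDR threshold are not given in the sources used here. Column 7 of each list is the peak caller's signal value as deposited by the authors, whose scaling is not given, so it was used to rank and describe peaks within a list. Column 9 was deposited as a −log10 q-value and column 10 as the offset of the summit from the peak's start. The signal values are the authors' own throughout. Each replicate list and the combined list held exactly 30000 peaks. The thresholded list was checked to be the 634 peaks of highest signal in the combined list, all at its highest −log10 q-value of 1.92, a value shared by 791 peaks of that list. The lists carry no read counts, so the depth of each replicate is unknown and no counting interval could be given for a peak.

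Peak coordinates were set against the Ensembl release 115 annotation and the RefSeq sequence of the WBcel235 assembly, which is the same sequence as ce11; every peak ended inside the reference chromosomes. Coordinates are given 1-based. Summits on the mitochondrial genome were left out of every test of position, chromosome, gene list and motif. Peaks were called shared between replicates when they overlapped by 1 bp or more. The overlap was measured for the 634 strongest peaks of each replicate and tested one-sided against 10000 circular shifts of the replicate 1 peaks within their chromosomes. A summit was placed at a gene when it lay from 1500 bp upstream to 500 bp downstream of the annotated 5′ end of a protein-coding gene, and otherwise in an exon, an intron or intergenic sequence. Shares of positions were tested two-sided against 100000 circular shifts of the summits. The p-values of these shifts, and of Fisher's test over genes, treat peaks or genes as the units; they do not measure the spread between embryo samples.

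A gene with a thresholded summit in its window was called a target gene. Membership of 27 gene lists was tested with Fisher's exact test, two-sided, against all 19973 nuclear protein-coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The share of peaks on X was tested with an exact binomial test against the share of protein-coding genes on X, with 95% exact (Clopper-Pearson) intervals that cover counting error only. The Sox consensus WWCAAWG was searched on either strand within 50 bp of each summit and within 50 bp of the point 500 bp below it, and compared with McNemar's exact test. All words of 6 bases were compared between the same windows, taken as unpaired, with Fisher's exact test and Benjamini-Hochberg adjustment. Peaks around sem-2 and unc-119, which the transgene carries in added copies, were counted within 40 kb either side of each gene and set beside all other windows of the same size.

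The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names genes with a summit of any of the 25 strongest thresholded peaks in their window, up to 4 members of each list that passed its test and up to 2 of each list that did not, in order of signal. It also names sem-2, unc-119, hlh-8, lin-39, mab-5, hlh-1, egl-17, egl-15 and the other Sox genes whatever their values. The comparison with genes for tRNA, small nucleolar RNA (snoRNA) and small nuclear RNA (snRNA), within 100 bp of the summit, was added after the positions of the strongest peaks had been seen, as were the alternatives that leave out these peaks or the mitochondrial peaks. Alternatives fixed in advance were a stricter signal cut, other windows, other overlaps, other backgrounds, 10000 matched gene sets, other flanks, 1000 dinucleotide shuffles, and each replicate alone.

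The statistics were tested on simulated data. With the odds of histone genes raised 10 times among 19973 genes, the histone list was called in 99.5% of 200 simulations, and another list was called in 7.5% of them. With random targets it was called in 0.5% of simulations, and another list in 2.5%. Simulated targets were drawn independently of each other, so these rates do not cover neighbouring genes that share a summit. Among 617 summits placed at random, the share at 5′ ends was called in 2% of 100 simulations, and in 100% when 20% of the summits were moved to 5′ ends. A consensus or a word planted in 10% of 617 windows was called in 100% of 20 simulations, with 0.6 other words called per simulation. Both sets of simulated windows came from random genome positions. These rates therefore do not cover summits and flanks that differ in G and C content, as the real windows did. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.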

Results

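SEM-2 is the SoxC transcription factor of C. elegans, known from genetics to promote the sex myoblast fate in the postembryonic mesoderm. Its binding was profiled by ChIP-seq in mixed-stage embryos collected by bleaching, from a strain in which a transgene supplies SEM-2 fused to eGFP and a working copy of unc-119 as its marker. There was 1 group of 2 biological replicates, numbered 1 and 3, and each gave a list of 30000 peaks ranked by signal value. The thresholded list of both replicates together held 634 peaks with a median width of 436 bp, of which 617 lay on the nuclear chromosomes and 17 on the mitochondrial genome. The depth of the libraries is unknown, since the lists carry no read counts.

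The first question was how far the replicates shared their peaks. The nuclear peaks that led the combined data also led each replicate. The peak in an intron of frm-7 (chromosome V, 12303397 to 12303873, signal 1583), beside a pair of snoRNA genes, was the strongest nuclear peak and ranked 16 in replicate 1 and 2 in replicate 3. The intergenic peak at the snoRNA gene W03C9.9 (chromosome II, 11960610 to 11961040, signal 1481) ranked 18 in replicate 1 and 1 in replicate 3. Both were singled out after their values were seen. In contrast, the 17 mitochondrial peaks of the thresholded list had no counterpart in replicate 3.

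Of the 634 strongest peaks of replicate 1, 362 (57.1%) overlapped the 634 strongest of replicate 3, against a mean of 0.505% and a highest value of 9.94% after shifting (one-sided permutation test, p = 1e-04, the smallest that 10000 shifts can give). The overlap was 73% for the 100 strongest peaks and 35.3% for the 5000 strongest (4.29% after shifting), and it was 51.6% for the full lists of 30000 (23.5% after shifting). Of the 634 thresholded peaks, 349 overlapped a peak among the 634 strongest of both replicates. A further 162 did so for replicate 1 only, 78 for replicate 3 only, and 45 for neither. The share found in both replicates differed between classes of peaks, as given below. Across the 607 nuclear thresholded peaks found in both full lists, the signal values of the replicates had a Spearman correlation of 0.597 across peaks, which are not independent replicates.

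**Figure D1:**
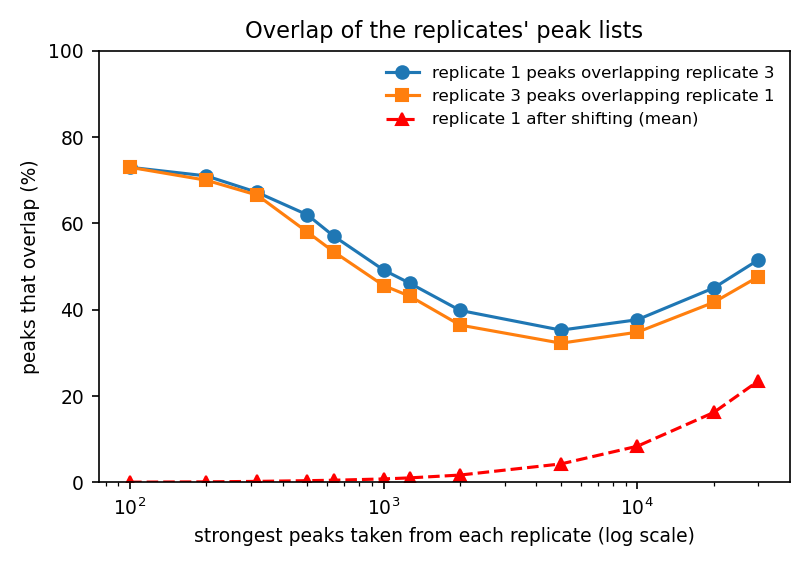
Share of peaks (%) that overlap the other replicate, against the number of strongest peaks taken from each replicate (log scale). Circles are replicate 1, squares replicate 3 and triangles the mean of replicate 1 after shifting; the share is 73% at 100 peaks and 57.1% of replicate 1 at 634 peaks.

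The strongest nuclear peaks lay at genes for small non-coding RNAs. Of the 617 nuclear summits, 192 (31.1%) lay within 100 bp of a tRNA gene, 60 (9.72%) of a snoRNA gene and 16 (2.59%) of a snRNA gene, where shifted positions gave 0.185%, 0.117% and 0.0352%. The snoRNA peaks had the highest median signal of these classes, 485, followed by tRNA peaks at 293 and snRNA peaks at 242, while the 279 peaks away from any annotated RNA gene had a median of 182. Of the 100 strongest nuclear peaks, 42 lay at tRNA genes and 35 at snoRNA genes. Of the snoRNA peaks, 85% overlapped the strongest peaks of both replicates, as did 72.4% of tRNA peaks and 62.5% of snRNA peaks. For the 279 peaks away from any annotated RNA gene, this share was 38.0%. Counted by gene, 196 of 612 nuclear tRNA genes, 59 of 346 snoRNA genes (17.1%) and 13 snRNA genes (10.1%) held a summit.

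This comparison was added after the positions of the strongest peaks had been seen. As 1 class, the 268 peaks at these genes made up 43.4% of nuclear summits against 0.337% after shifting (two-sided permutation test, p = 2e-05, the smallest that 100000 shifts can give; adjusted p = 2.9e-05 over 10 classes). The share was 45.4% among the strongest peaks of replicate 1 and 32.8% among those of replicate 3. It was 65.1% among thresholded peaks with a signal above the median and 25.45% when the summit had to lie inside the RNA gene. Peaks at other genes annotated as ncRNA numbered 64 (10.4%, against 2.28% after shifting) and peaks at miRNA genes 6 (0.972%, against 0.0766%). Each summit was counted in 1 class only, so summits also near a tRNA, snoRNA, snRNA or miRNA gene are not among the 64.

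Named genes beside the strongest peaks were mostly neighbours of snoRNA genes. Among the 25 strongest thresholded peaks, 5 had a summit in the window of a protein-coding gene. The peak upstream of sre-23, a chemoreceptor gene, had a signal of 1292 (chromosome I, 8259356 to 8259758, intergenic) and lay at the snoRNA gene ZK265.10. An intergenic peak with a signal of 1006 (chromosome III, 8043800 to 8044143) was shared by K12H4.5, K12H4.6 and the signal peptidase subunit gene spcs-3. It had no gene of the RNA classes above within 100 bp. The peaks assigned to the mitochondrial ribosomal protein gene mrps-28 (signal 899.9, chromosome V, 19643033 to 19643433, in an intron of Y43F8C.7), to T02E1.2 (signal 894, chromosome I, 8224224 to 8224596, intergenic) and to D1046.2 (signal 859, chromosome IV, 8927057 to 8927377, in an intron of cfim-2) each lay at a snoRNA gene. All 5 peaks ranked within the 13 strongest of replicate 3 and the 32 strongest of replicate 1.

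Summits were also concentrated at the 5′ ends of protein-coding genes. A share of 50.1% (309 of 617) lay in a 5′ window, against 32.6% after shifting (two-sided permutation test, p = 2e-05, the smallest possible; adjusted p = 2.9e-05). Exons outside these windows held 36 summits (5.83%, against 18.9%; permutation test, adjusted p = 2.9e-05) and introns 165 (26.7%, against 27.1%; adjusted p = 0.875). The exon share was 4.73% among the strongest peaks of replicate 1, 12.8% among those of replicate 3 and 2.33% among thresholded peaks with a signal above the median. Intergenic sequence held 107 summits (17.3%, against 21.4%; permutation test, adjusted p = 0.0241), a difference that was not past the threshold among the strongest peaks of replicate 3 (19.9%, against 21.6%; adjusted p = 0.385) or among thresholded peaks with a signal above the median (21.3%, against 21.7%; adjusted p = 0.921). Among the 349 nuclear peaks away from tRNA, snoRNA and snRNA genes, 58.7% lay in a 5′ window, 9.74% in exons, 19.5% in introns (against 27.4% after shifting; permutation test, adjusted p = 0.0023) and 42 peaks in intergenic sequence (against a mean of 72.4; adjusted p = 0.00016). With a window from 500 bp upstream to 250 bp downstream, the share of all nuclear summits was 29.2%, against 13.6% after shifting.

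**Figure D2:**
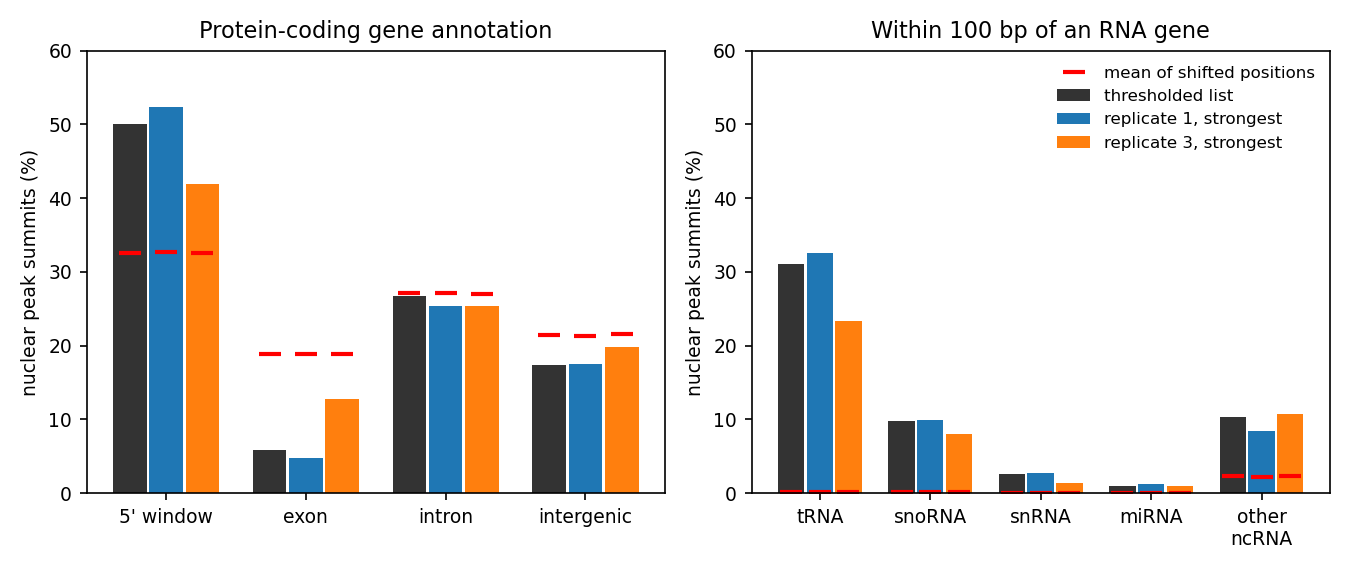
Share of nuclear summits (%) by position relative to protein-coding genes (left) and within 100 bp of RNA genes (right), for the thresholded list and the strongest peaks of each replicate. Bars are observed shares and red marks the means of shifted positions; tRNA genes hold 31.1% of thresholded summits, against 0.185% after shifting.

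The X chromosome carried more peaks than its share of genes. It held 146 of 617 nuclear peaks (23.7%, 95% exact interval 20.4 to 27.2), where 13.7% of protein-coding genes lie on X (exact binomial test, two-sided, p = 3.2e-11). Of the other chromosomes, I held 109 peaks, III 108, II 93, IV 83 and V 78. Among the 192 tRNA peaks, 84 (43.8%) were on X, and 276 of 612 tRNA genes (45.1%) are on X (exact binomial test, p = 0.718). A single snoRNA peak of 60 was on X. Without the tRNA peaks, X held 62 of 425 nuclear peaks (14.6%, interval 11.4 to 18.3), not past the threshold against the share of protein-coding genes (exact binomial test, p = 0.572). Without the snoRNA and snRNA peaks as well, it held 61 of 349 (17.5%, exact binomial test, p = 0.0426), where X makes up 17.7% of the length of the nuclear chromosomes.

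Histone genes and cytosolic ribosomal protein genes were the protein-coding groups most often found among targets. In all, 434 protein-coding genes (2.17%) had a thresholded summit in their window, and 315 remained without the peaks at tRNA, snoRNA and snRNA genes. Of 72 histone genes, 16 were targets, 10.2 times the number expected (odds ratio 13.3, 95% interval 7.07 to 23.8; Fisher's exact test, adjusted p = 6.9e-11 over 27 lists). These genes shared summits, which Fisher's test does not allow for, so this interval is too narrow and this p-value too small. Of 76 cytosolic ribosomal protein genes, 12 were targets, 7.27 times the number expected (odds ratio 8.65, interval 4.22 to 16.3; Fisher's exact test, adjusted p = 1.1e-06). None of the histone or ribosomal protein peaks lay at a tRNA, snoRNA or snRNA gene. Chemoreceptor genes were underrepresented, with 10 targets among 1309 genes where 28.4 were expected (Fisher's exact test, adjusted p = 0.00066).

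The 16 histone genes shared 8 summits, of which 5 lay in histone coding sequence and 3 in intergenic sequence. The strongest, with a signal of 399 (chromosome IV, 8334229 to 8334828), had its summit in the coding sequence of his-32 and also lay in the window of his-31. A peak with a signal of 283 (chromosome IV, 7487660 to 7488084) had its summit in the coding sequence of his-60 and was shared with his-59. Histone genes occur in near-identical copies, so reads may have been split between them and the assignment to a copy is uncertain. With each summit given to the nearest 5′ end within 5000 bp, which changes both the reach and the number of genes per summit, 7 histone genes were targets (3.84 times the number expected, Fisher's exact test, adjusted p = 0.028), and replicate 3 alone gave 5.75 times (adjusted p = 0.0041).

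The 12 ribosomal protein genes each had a peak upstream, at a median of 266 bp from the 5′ end. The strongest were at rpl-3 (signal 417, chromosome III, 3867480 to 3867696), rpl-15 (signal 373, chromosome IV, 654833 to 654969), rpl-20 (signal 238, chromosome IV, 4749826 to 4750261) and rps-28 (signal 227, chromosome IV, 1659039 to 1659474), all intergenic. The rps-28 window ranked 226 in replicate 1 and 23306 in replicate 3, and replicate 3 alone gave 7 targets among the 76 genes (Fisher's exact test, adjusted p = 0.0041). Among peaks with a signal above the median, the list was not past the threshold (4 of 76 genes, 4.89 times the number expected, Fisher's exact test, adjusted p = 0.0824), and over the other alternatives the ratio ranged from 3.54 to 13.8. Some of the 12 genes, such as rpl-20, had another gene's 5′ end nearer to the summit. With each summit given to the nearest 5′ end within 5000 bp, 7 of 76 genes were targets (3.64 times the number expected, Fisher's exact test, adjusted p = 0.028).

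Of 30 Wnt pathway genes, 4 were targets, 6.14 times the number expected (odds ratio 6.98, interval 1.76 to 20.2; Fisher's exact test, adjusted p = 0.026). These were mom-1, which is needed for Wnt secretion (signal 566, chromosome X, 6292223 to 6292512, intergenic, at a tRNA gene), the beta-catenin gene hmp-2 (signal 304, chromosome I, 14737245 to 14737680, intergenic), the planar polarity gene vang-1 (signal 227, chromosome X, 2885347 to 2885782, intergenic) and the TCF gene pop-1 (signal 168, chromosome I, 2831421 to 2831856, intergenic). The vang-1 and pop-1 peaks lay at other non-coding RNA genes. In the order named, the summits were 738, 1419, 293 and 1328 bp upstream. The mom-1 summit was nearer to lev-9 (642 bp) and the hmp-2 summit to K05C4.7 (239 bp). The call was lost in 5 of 8 alternatives, with 2.92 to 9.29 times the number expected and exact adjusted p from 0.0544 to 1, among them the one without peaks at tRNA, snoRNA and snRNA genes (3 of 30 genes, 6.34 times the number expected, adjusted p = 0.0777). The underrepresentation of chemoreceptor genes was lost against genes with any peak of the combined list (0.876 times the number expected, Fisher's exact test, adjusted p = 1) and among peaks with a signal above the median (0.639 times, adjusted p = 0.879). The chemoreceptor genes with the strongest peaks after sre-23 were srd-43 (signal 618) and srg-64 (signal 408), both at tRNA genes, and sre-1 (signal 369).

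No gene of the lists for differentiated tissues, Hox genes, Notch and TGF-beta signalling had a thresholded summit in its window. There were 0 targets among 35 genes of body wall muscle structure, 21 of the pharynx, 28 of the intestine, 36 of the epidermis, 37 of neuronal differentiation, 38 neuronal fate regulators, 17 glial genes, 11 Hox genes and cofactors, 24 Notch and 18 TGF-beta pathway genes, 25 bHLH genes, 31 major sperm protein genes, 38 insulin-like peptide genes and 5 Sox genes. With lists of this size, at most 0.826 targets were expected by chance in each, so no list was detectably low when taken alone. The lists were not tested together, so a joint shortage was not assessed. With the nearest 5′ end within 5000 bp in place of the window, there were 2 targets each among the neuronal differentiation, neuronal fate and Notch genes and 1 each among the body wall muscle, Hox and insulin-like peptide genes. Replicate 3 alone gave 1 neuronal fate and 1 bHLH target, and none of these lists passed the test in any alternative.

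In the list of 26 mesoderm and M lineage regulators, 2 were targets (Fisher's exact test, adjusted p = 0.42). These were pop-1 and the FGF gene egl-17, whose peak (signal 524, chromosome X, 489796 to 489991) lay in an egl-17 intron at a tRNA gene. egl-17 was also the single target among 18 EGF, FGF and Ras pathway genes (Fisher's exact test, adjusted p = 0.98). The M lineage regulator hlh-8, the Hox genes lin-39 and mab-5 and the muscle regulator hlh-1 had no thresholded peak in their windows. Their best peaks in the combined list ranked 23377, 19747, 23301 and 8595. The FGF receptor gene egl-15 had no peak in its window in any list. Of the Sox genes, egl-13 had a best rank of 7697, sox-2 of 10688 and sox-3 of 27521, and sox-4 had no peak in its window.

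The remaining lists did not pass the test. Heat shock and chaperone genes had 2 targets among 20 (Fisher's exact test, adjusted p = 0.311), hsp-60 (signal 296) and hsp-1 (signal 169), and the list passed in replicate 1 alone with 3 targets (adjusted p = 0.0498). Cell cycle genes had lin-35, the Rb gene (signal 271), as the single target among 43, germline and maternal genes had mex-1 (signal 264) among 32, and ceh homeobox genes had ceh-38 (signal 157, in the 5′ UTR) among 63 (exact adjusted p = 1 each). Nuclear hormone receptor genes had 2 targets among 269 (exact adjusted p = 0.459), nhr-255 (signal 408, at a tRNA gene) and nhr-47 (signal 178). Cuticle collagen genes had 2 among 156 (exact adjusted p = 1), col-85 (signal 503) and col-185 (signal 344), both at tRNA genes. F-box genes had 2 among 322 (exact adjusted p = 0.281), fbxb-85 (signal 263) and fbxc-44 (signal 164). The windows of ceh-38, hsp-1 and nhr-47 ranked 2544, 1995 and 810 in replicate 3, and fbxc-44 had no peak there.

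**Figure D3:**
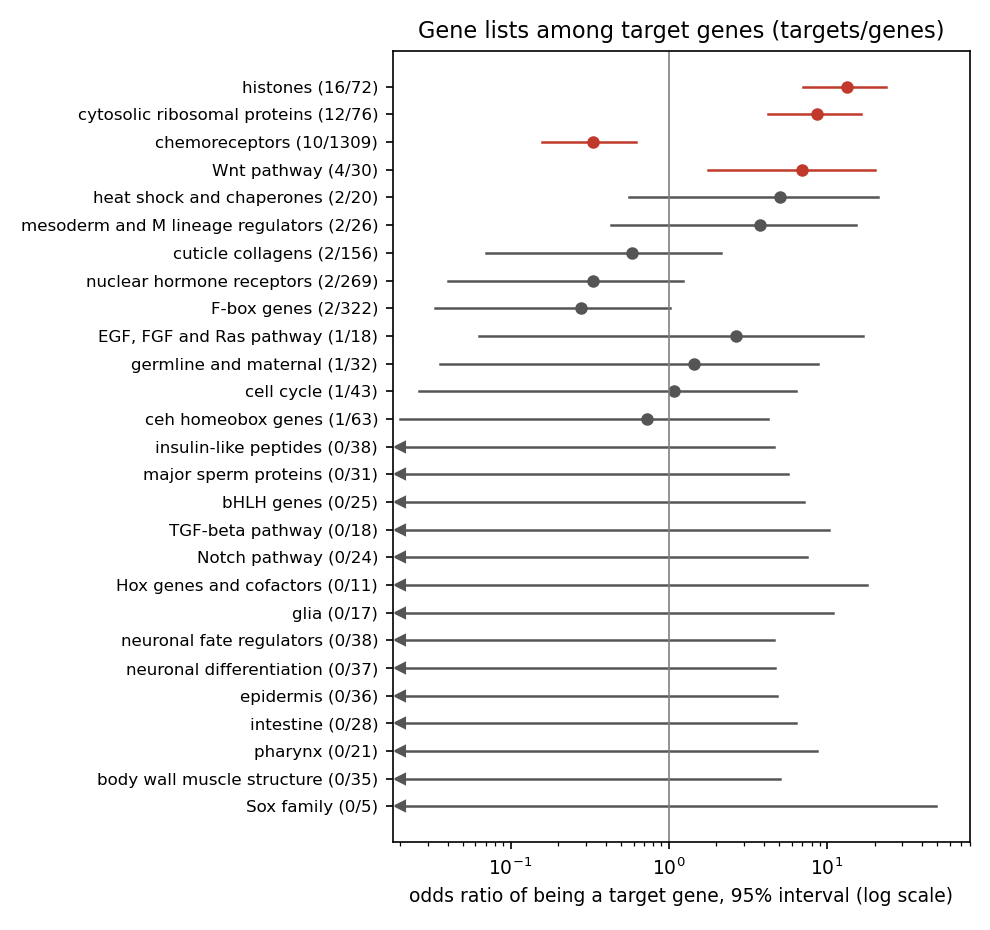
Odds ratio of being a target gene for each of the 27 gene lists, with 95% exact intervals (log scale); targets and genes are given beside each name, arrows mark lists with 0 targets, and red marks lists with an adjusted p under 0.05. Histones (16 of 72), cytosolic ribosomal proteins (12 of 76) and the Wnt pathway (4 of 30) lie above 1, and chemoreceptors (10 of 1309) below.

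The Sox consensus was less frequent at summits than beside them. WWCAAWG occurred within 50 bp of 39 of 617 nuclear summits (6.32%) and in 93 of the windows 500 bp below (15.1%). It was present only at the summit in 35 pairs and only in the flank in 89 (McNemar's exact test, two-sided, p = 1.3e-06). Summit windows were richer in G and C, at 50.2% ± 7.90 against 36.1% ± 8.62 in the flanks (SD, n = 617 windows), and shuffles of the summit windows that kept their dinucleotides held the consensus in 10.5% of windows (permutation p = 0.002, the smallest that 1000 shuffles can give). With ACAAWG as the consensus, the shares were 7.29% and 10.4%, not past the threshold (McNemar's exact test, p = 0.0814).

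Of 2080 words of 6 bases, 433 were more frequent at summits and 306 less frequent (Fisher's exact test, adjusted p under 0.05). The test took summit and flank of a peak as unpaired, and identical tRNA gene copies as separate windows. No shuffles were run for words, so the difference in G and C content was not taken into account. CGAACC was found in 111 summit windows and 16 flanks (exact adjusted p = 8.1e-18), and GTTCGA in 20.9% of summit windows and 5.67% of flanks (adjusted p = 1.4e-13); both lie in the B box, an internal promoter element of tRNA genes. ACACAC was found in 102 and 13 (exact adjusted p = 2.4e-17) and CGCACG in 58 and 2 (adjusted p = 1.0e-13). In the 349 windows away from tRNA, snoRNA and snRNA genes, the leading words were ACACAC (71 against 5 windows), CCGCAC (51 against 2) and GCACAC (62 against 6).

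The tagged gene itself carried peaks. In the thresholded list, 3 peaks had their summits inside sem-2 (chromosome I, 5204530 to 5219815, minus strand), against 1 among the strongest peaks of replicate 1 and 5 among those of replicate 3. These lay in coding sequence (5205297 to 5205732, signal 227, rank 300, and 5206319 to 5206754, signal 172, rank 479) and in an intron (5209851 to 5210286, signal 189, rank 407). A further peak lay in an intron of spd-5 (5176214 to 5176649, signal 191, rank 400). The transgene also holds sem-2, and native and added copies were not told apart, since no reads were analysed. None of the thresholded summits lay in the 5′ window of sem-2.

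The 4 peaks within 40 kb of sem-2 compared with a mean of 0.581 in the other 1047 windows of that size, of which 9 (0.86%) held as many. Among the strongest peaks of replicate 3 there were 6, a number reached by 1 other window, and among those of replicate 1 there were 3, reached by 40. The full combined list had 28 peaks in this window, against a mean of 28.5 in the others. The marker gene unc-119 (chromosome III, 10902641 to 10908935), also supplied by the transgene, had 0 thresholded peaks within 40 kb, where other windows of that size held a mean of 0.531, and its own best peak in the combined list ranked 8611 in its 5′ window.

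**Figure D4:**
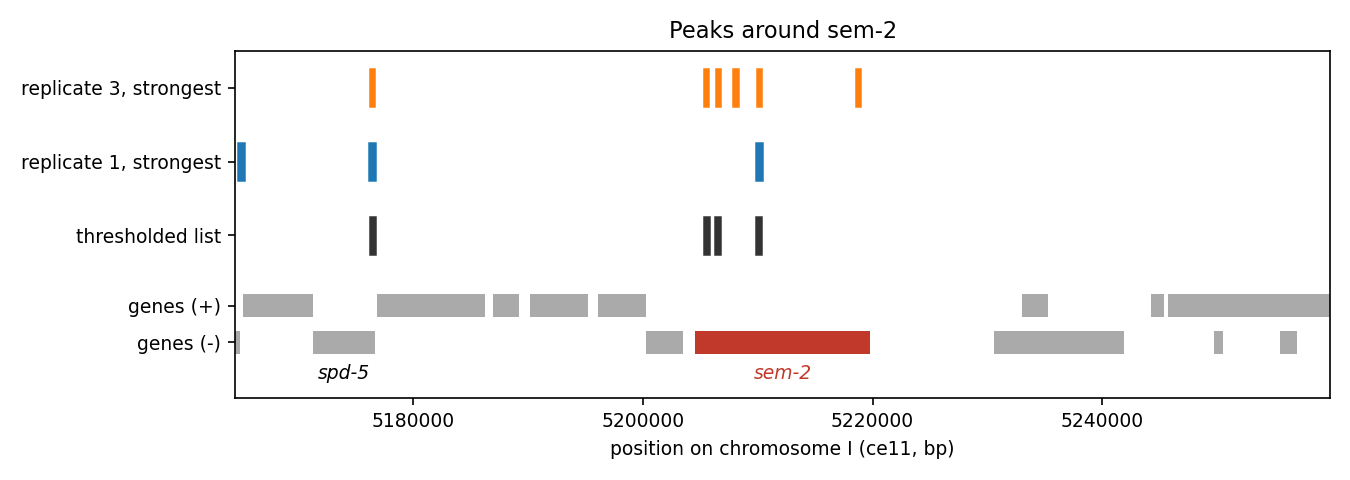
Map of chromosome I around sem-2 (ce11, bp), with protein-coding genes by strand and the peaks of the thresholded list and of the strongest peaks of each replicate. The thresholded list has 3 peaks in sem-2 and 1 in spd-5, replicate 1 has 1 in sem-2 and replicate 3 has 5.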

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

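The tests of single-copy tRNA genes, of the Sox consensus at small RNA genes, of X without tRNA peaks and of the ranks of the mitochondrial peaks were chosen after the results were seen. The test of identical tRNA copies was set out before its own result.

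Peaks on the mitochondrial genome were used in no test of position, chromosome, gene list or motif: there were 17 in the thresholded list and 21 in the list of replicate 1, while replicate 3 had 0. In replicate 1 all 21 stood among its 634 strongest peaks and covered 10708 bp; peaks so close together are not independent counts, and the difference between the 2 replicates was not tested. A candidate explanation is that replicate 3 held such peaks below the end of its list. The median rank of the mitochondrial peaks in replicate 1 was 11 of 30000, so their signal was strong there. That rank cannot show how weak the signal was in replicate 3, so it does not decide this explanation. Removal of mitochondrial reads before the peaks of replicate 3 were called, or a different share of mitochondrial DNA in the libraries, stays open, since no read counts were analysed.

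The peaks at tRNA, snoRNA and snRNA genes may in part reflect reads shared between identical tRNA genes. Of 472 tRNA genes whose sequence occurs more than once in the genome, 36.4% held a summit, against 17.1% of 140 genes with a single copy (odds ratio 2.77, 95% interval 1.69 to 4.67; Fisher's exact test, p = 1.3e-05), as such sharing would give if reads with several matches were kept. How the aligner treated such reads is not given, and genes that share reads are not independent units for this test. Sharing between identical copies does not account for all of the pattern. At single-copy tRNA genes lay 23 summits, where 10000 shifts gave a mean of 0.262 and at most 7. Near-identical copies were not searched, so sharing of reads with those stays open. Binding to a Sox site was a further candidate cause. WWCAAWG lay in 5.22% of the 268 summit windows at tRNA, snoRNA and snRNA genes. Of their dinucleotide shuffles, 95% held it in 6.71% to 13.4% of windows, so it was not enriched close to these summits. These values argue against binding to WWCAAWG within 50 bp of the summit as the cause of most of these 268 peaks. All other nuclear peaks were also below their shuffles (7.16%, against 8.02% to 14.3%), so the shortage was not particular to small RNA genes. Windows at identical tRNA copies are not independent, and neither ACAAWG nor wider windows were tried at small RNA genes. Binding to other Sox sites, or to sites further from the summit, was therefore not decided. Enrichment of open, highly transcribed genes by the antibody or in the absence of the fusion protein stays open, because no GFP-free immunoprecipitation was analysed here; no difference between biological groups was tested, as the design has 1 group.

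The excess of peaks on X may come from the number of tRNA genes there. X held 23.7% of nuclear peaks, and 14.6% (interval 11.4 to 18.3) once tRNA peaks were left out, an interval that includes the 13.7% of protein-coding genes on X. A summit was held by 85 of 276 tRNA genes on X (30.8%), and 111 of 336 on the autosomes (Fisher's exact test, p = 0.602). Without snoRNA and snRNA peaks too, X held 17.5% (exact binomial test, p = 0.0426), close to its 17.7% of chromosome length. In that remainder, X held 25 of 64 peaks at other genes annotated as ncRNA. It held 34 of 279 peaks away from tRNA, snoRNA, snRNA, miRNA and ncRNA genes. The difference between these was not tested.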

How the results depend on the processing

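The alternatives without mitochondrial peaks or without peaks at small RNA genes or tRNA genes, every test of the share at small RNA genes and the single-replicate counts near sem-2 were chosen after the data were seen. Of 50 alternative values of the main results, 42 kept their direction and their side of the threshold, or a count within 1.5 times. The number of peaks was 317 above the median signal, 349 among the strongest of both replicates and 366 without peaks at tRNA, snoRNA and snRNA genes; these follow from keeping fewer peaks. Target genes numbered 228 with the window from 500 bp upstream to 250 bp downstream and 215 above the median signal. The number of enriched lists fell from 3 to 1 above the median signal, where fewer genes were targets. The difference in the Sox consensus, -8.75 percentage points, was -3.08 with ACAAWG (McNemar's exact test, p = 0.0814); the cause was not tested. The share on X was 14.6% without peaks at tRNA genes. From either replicate alone, shares ranged from 41.96% to 52.4% at 5′ ends, from 32.8% to 45.4% at small RNA genes and from 22.2% to 25.7% on X, target genes from 338 to 441, enriched lists from 3 to 4, the consensus difference from -10.4 to -7.67 points and peaks near sem-2 from 3 to 6. The 441 target genes of replicate 1 and the 338 of replicate 3 had 222 in common. Of the 434 thresholded target genes, 370 were targets in replicate 1 alone and 257 in replicate 3 alone. The replicate overlap needs both replicates, so none could be left out; it ranged from 46.1% to 67.2%. No paired analysis was possible because there is 1 group. The lists give no read counts, so what depth limits could not be measured, and weak peaks beyond 30000 per list are not seen.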

Other observations

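All tests in this part were chosen after the results were seen, and the genes named here were singled out after their values were seen.

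Neither the place of snoRNA genes nor the isotype of tRNA genes passed a test for a difference in peaks. Of 216 snoRNA genes inside protein-coding genes, 34 held a summit (15.7%), and of 130 outside, 25 did (19.2%; Fisher's exact test, p = 0.461). Of 20 tRNA isotypes tested, none differed from the others after adjustment (Fisher's exact test, lowest adjusted p = 0.933). Alanine tRNA genes had the highest share, 16 of 34 (47.1%), and glutamine tRNA genes the lowest, 5 of 27 (18.5%). Of the tRNA genes with a summit among the strongest peaks, 205 in replicate 1 and 151 in replicate 3, 142 were shared. Of the 6 peaks at miRNA genes, the strongest were at cel-mir-51 (signal 1230, chromosome IV, 11025836 to 11026451) and cel-mir-52 (signal 981, chromosome IV, 14033688 to 14034404), both intergenic.

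The word GCACAC at summits away from small RNA genes may be part of a longer element. Within 75 bp of these 349 summits it occurred 90 times, and 19 of these (21.1%) had GCAA 3 to 9 bases before it, against 1478 of 29566 occurrences in the genome (5.00%; odds ratio 5.14 for summits over the rest, 95% interval 2.92 to 8.65; Fisher's exact test, p = 8.2e-08). The pair was seen in 17 windows. It was noticed and tested in the same peaks, so it remains a hypothesis, and the protein that would bind it was not tested.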
